A study of Homo sapiens with 3 samples.

How the data were processed

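RNA sequencing data of hStau1-associated RNA from HEK293T cells were analysed, with 1 library for each of 3 groups (wild-type hStau1, mutant hStau1, and wild-type hStau1 with RNase T1). Groups were taken from the sample titles. Per the labels' protocols, RNA was released from calmodulin-agarose with proteinase K, 100 ng of each RNA entered an mRNA sequencing protocol without selection of poly(A) RNA, and fragmentation was omitted for the RNase T1 sample, whose RNA was already about 100 nt long. Gel purification of the libraries excluded small RNAs, and single reads of 100 nt were made on a HiSeq2000, per the labels' protocols. A library of the tag alone was not analysed here, so binding to the tag or to the resin is not subtracted from any value. Nor was a library of total RNA, so no value is corrected for the level of an RNA in the cells.

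The deposited files hold raw read counts per gene, per the file headers, with 23226 rows each, keyed by NCBI gene ID with a symbol, a cytogenetic band and a gene type. The values were whole numbers whose totals differed between files. Whether they count all aligned reads or only unique or collapsed ones is not given in the sources used here. Reads were aligned with BWA to hg19, per the submitters' processing notes. The version of the aligner, the counting tool, its treatment of strand and of reads with several matches, and the annotation release are not given in the sources used here. Reads from overlapping or near-identical genes can therefore be split, pooled or counted for more than 1 gene in these counts. Some genes that share sequence are reported as uncertain. No search was made for sequences similar to the other genes, the ribosomal protein genes among them. The files hold 26 rows whose symbol had turned into a date, kept under their gene ID, and 2 symbols that stand on more than 1 row. No row carries a gene of the mitochondrial genome, so the lists of mitochondrial mRNAs and rRNAs fixed beforehand were not analysed here. In each file 10 rows name no gene. They held 0.0397%, 0.0395% and 0.0222% of reads for wild type, mutant and RNase T1, and were left out of library sizes and comparisons.

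Because each group has 1 library, no test across replicates could be made and none of the count models for replicates was fitted. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, computed over the 3 libraries (1.22, 1.21 and 0.678 for wild type, mutant and RNase T1). For each pair of libraries the log2 ratio of scaled counts was computed with a prior count of 0.5 in each library. Its interval is the exact (Clopper-Pearson) 95% interval of the share of the pair's reads in the first library, and compares these libraries, not the conditions. A gene was measured with at least 50 reads in the 2 libraries together, and called higher or lower when the whole interval lay beyond 2-fold. A count of 0 was read as up to 3 counts. Shares of reads have exact binomial 95% intervals. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

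The depth limits what could be called. The median gene with reads had 4 reads with wild type, 4 with mutant and 2 after RNase T1, and the floor of 3 counts corresponds to 19.9, 18.2 and 21.5 CPM (counts scaled to a common library total). The method was tested on simulated counts drawn for 23216 genes at the real levels, with 200 changed genes. For wild type against mutant it called 58 of 66 genes changed 4-fold, 66 of 66 changed 8-fold and 0 of 64 changed 2-fold, and 0 of 1300 unchanged genes. For RNase T1 against wild type it called 49 of 65 genes changed 4-fold, 64 of 64 changed 8-fold, 2 of 60 changed 2-fold and 0 of 602 unchanged genes. Intervals held the true ratio for 97.3% and 97.5% of measured genes. The draws were Poisson counts at known library sizes, without variation from PCR, preparation or scaling. These results therefore check the computation and are not error rates of the real calls. The rule asks for an interval wholly beyond 2-fold, so by construction a true change of 2-fold is not called except by chance, at any depth.

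The comparisons, the filter, the thresholds, the alternatives, 25 gene lists and the rule for named genes were fixed before the data were examined. Named genes were, for wild type against mutant and for RNase T1 against wild type, up to 12 in each direction among called genes with at least 200 reads, ranked by the bound of the interval nearest 0. To these were added STAU1 and STAU2, the 5 genes with most reads in each library, and from each list the 2 members with the highest and the 2 with the lowest ratio and the 2 with most reads, of which a part is printed. Lists covered, among others, ribosomal proteins, translation, metabolism, chaperones, histones, cell cycle, KRAB zinc fingers, chromatin, cytoskeleton and markers of other tissues. The median log2 ratio of the measured members was placed among 10000 random lists of the same size matched over 20 bins of mean expression, as a description of these libraries. Overlaps of comparisons were set beside the product of the list sizes over the genes measured in both, and beside 100 simulations of unchanged libraries.

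Lengths and GC content came from GENCODE 29 transcripts on GRCh38, another build than that of the counts, so no coordinates were taken from it. For 18863 of 19070 coding genes (98.9%) the longest transcript matched by RefSeq accession or gene ID was used. Segments resembling Alu repeats, which descend from 7SL RNA, were found in 18007 annotated 3' UTRs of at least 50 nt by aligning the 7SL gene RN7SL1 with BLAST+ 2.17.0 at an E value of at most 1e-08. Hits on the same strand within 200 nt of each other and spanning at most 350 nt were merged. A 3' UTR with segments in both orientations is said to hold an inverted pair. Intervals of medians and correlations across genes in the closing section came from 2000 and 1000 bootstrap draws.

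Alternatives replaced the scaling (total counts, DESeq2 1.42.0 size factors, upper quartile), the filter (at least 1, 10 or 200 reads), the threshold (1.5-fold, 4-fold, or the point estimate alone), the features (without the MTRNR2L genes and the 100 features with most reads, or coding genes only), the depth (libraries thinned to 139391 reads) and the prior count (5). An alternative on isoforms did not apply, since the files count genes. A filter of at least 25 reads in the mutant library for RNase T1 against wild type was added after seeing the data. Random lists for wild type against mutant were also drawn, after the result was seen, for each member from the 50 genes nearest in read level among the 100 nearest in coding length, without the members of the list.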

Results

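RNA that copurified with human Staufen1 (hStau1) was sequenced from HEK293T cells. hStau1 binds double-stranded RNA and takes part in the transport, translation and decay of mRNAs, and HEK293T is a human embryonic kidney line that carries the SV40 large T antigen and is easily transfected. Cells received a plasmid for hStau1 fused to a tandem affinity purification tag, in the wild-type form or in a mutant form whose mutation is not given in the sources used here. RNA recovered with the tagged protein on calmodulin-agarose gave 3 libraries in 3 groups, with 1 library per group: wild-type hStau1, mutant hStau1, and wild-type hStau1 with RNase T1. RNase T1 cuts single-stranded RNA after G, so the last of these libraries holds the fragments that the enzyme left, about 100 nt long per the labels' protocols.

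The files counted 150990 reads for wild-type hStau1, 164639 for mutant hStau1 and 139422 for wild-type hStau1 with RNase T1, over 23216 named genes. Reads fell on 11911, 13530 and 12909 genes in the same order, and 555, 583 and 165 genes held at least 50 reads. The totals are low for the instrument, and whether they hold all reads or only unique or collapsed ones is not given in the sources used here, so shares, ratios and intervals refer to the counts as given. With 1 library per group the differences have no replicate check, the spread between replicates could not be measured and no p-value was computed. Intervals are exact 95% intervals that cover counting error only, since PCR reads without molecular identifiers are not independent molecules, and a count of 0 is read as allowing up to 3 counts.

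Protein-coding genes took most of the counted reads with untreated hStau1, while a single noncoding RNA led the counts after RNase T1. They held 94.6% of the reads with wild-type hStau1, 90.8% with mutant hStau1 and 64.0% after RNase T1. These are shares of reads counted in named genes, so they do not give the composition of the RNA. The mitochondrial genome had no genes among them, and the 1 row typed as ribosomal RNA had 0 reads. That 0 does not exclude reads from ribosomal RNA in other rows. RMRP, the RNA of the RNase MRP complex that processes ribosomal RNA precursors, took 1.18% of reads (1.13 to 1.24) with wild-type hStau1, 1.71% (1.65 to 1.78) with the mutant and 31.3% (31.1 to 31.6) after RNase T1. MAGT1, which encodes a magnesium transporter and oligosaccharyltransferase subunit, rose from 0.121% (0.104 to 0.139) of reads with wild-type hStau1 to 6.68% (6.55 to 6.81) after RNase T1. The MTRNR2L genes, nuclear copies resembling mitochondrial 16S ribosomal RNA, held 2.82%, 2.61% and 11.2% of reads for wild type, mutant and RNase T1. They are typed as protein-coding and made up 2.98%, 2.88% and 17.6% of the protein-coding reads, in the same order. The protein-coding shares above are therefore not shares of mRNA alone. Because their reads cannot be told from those of the mitochondrial RNA or of each other, their values are uncertain. The 10 features with most reads took 6.65% of the wild-type library, 9.91% of the mutant library and 53.6% of the RNase T1 library.

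**Figure D1:**
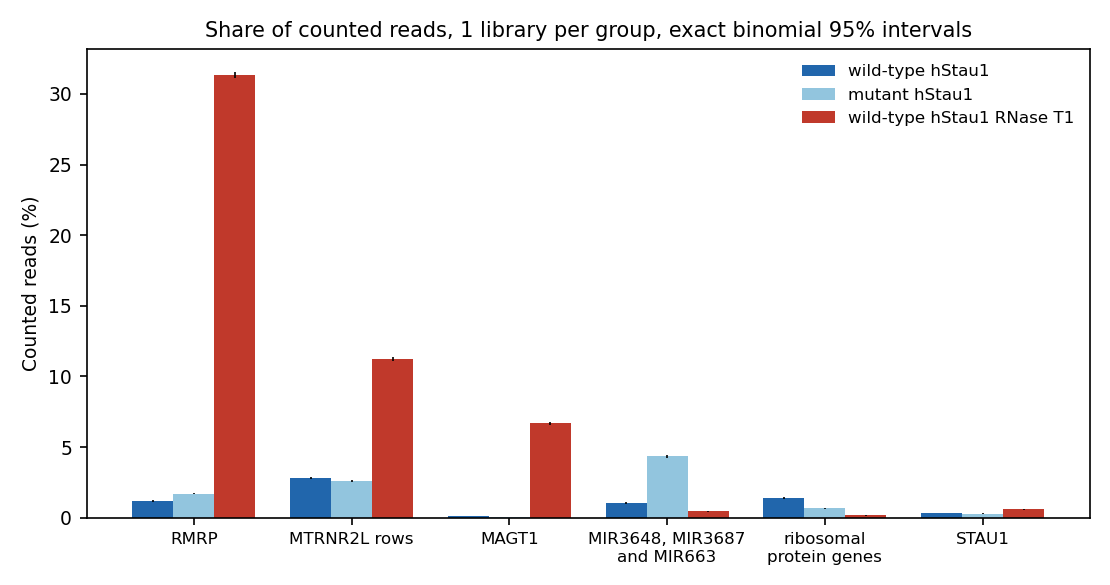
Share of counted reads (%) in 3 single genes and 3 gene sets for the 3 libraries, with exact binomial 95% intervals as error bars. RMRP reached 31.3% and MAGT1 6.68% after RNase T1, and the ribosomal protein genes held 1.40% with wild-type hStau1 against 0.672% with the mutant.

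STAU1, the gene of the tagged protein, held 505 reads with wild-type hStau1, 481 with the mutant and 837 after RNase T1. These are 0.335% (0.306 to 0.365), 0.292% (0.267 to 0.320) and 0.6% (0.561 to 0.642) of reads, and they can come from the endogenous gene or from the plasmid. The wild-type and mutant libraries differed by 0.18 on the log2 scale for STAU1, with an interval that reached 0. STAU2, the paralog of STAU1, had 0, 1 and 0 reads. Markers of skin, blood, liver and muscle held 2 reads with wild-type hStau1, 7 with the mutant and 18 after RNase T1.

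The comparison of wild type with mutant asks which RNAs differ in amount between RNA purified with the intact and with the altered protein. Total RNA of the transfected cells was not analysed here. A difference in association with the protein can therefore not be told from a difference in RNA level between the cells. mRNAs for ribosomal proteins stood higher with wild-type hStau1 as a group, as did single mRNAs such as PAICS and EIF5A, and the reads of a pair of microRNA loci stood higher with the mutant. PAICS, an enzyme of purine synthesis (gene 10606, 4q12), held 224 reads with wild type and 59 with mutant, a ratio of 4.07-fold (3.06 to 5.56). EIF5A, a translation factor modified by hypusine (gene 1984), held 252 and 77 reads, a ratio of 3.52-fold (2.73 to 4.62). MIR3648 held 455 reads with wild type and 4435 with mutant, a log2 ratio of -3.17 (-3.32 to -3.04), and MIR3687 held 281 and 998, a log2 ratio of -1.72 (-1.91 to -1.53).

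Of the 1467 genes measured, with at least 50 reads in both libraries together, 30 were called higher and 13 lower with wild-type hStau1, meaning that the whole interval lay beyond 2-fold. The median log2 ratio was 0.09. Among the genes with at least 200 reads, 8 were called higher and 2 lower. Besides PAICS and EIF5A, the higher ones were HIST2H3A and HIST2H3C, which encode histone H3 and carry identical counts in the files (log2 1.77, 1.38 to 2.18), EIF5AL1 (1.54), the mitochondrial phosphatase PGAM5 (1.43, 1.16 to 1.71), RPL13 (1.49) and RPS9 (1.41). The values of EIF5A and its near-identical copy EIF5AL1 are uncertain because reads could be split between the copies. Those of the histone H3 genes are uncertain because their identical counts may be the same reads counted for both. The histone H3 genes may therefore not be separate calls. The split of 30 higher against 13 lower became 34 against 7 with DESeq2 size factors and 21 against 16 with upper-quartile scaling. Upper-quartile scaling also ended the calls of 2 of the 10 genes with at least 200 reads.

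**Figure D2:**
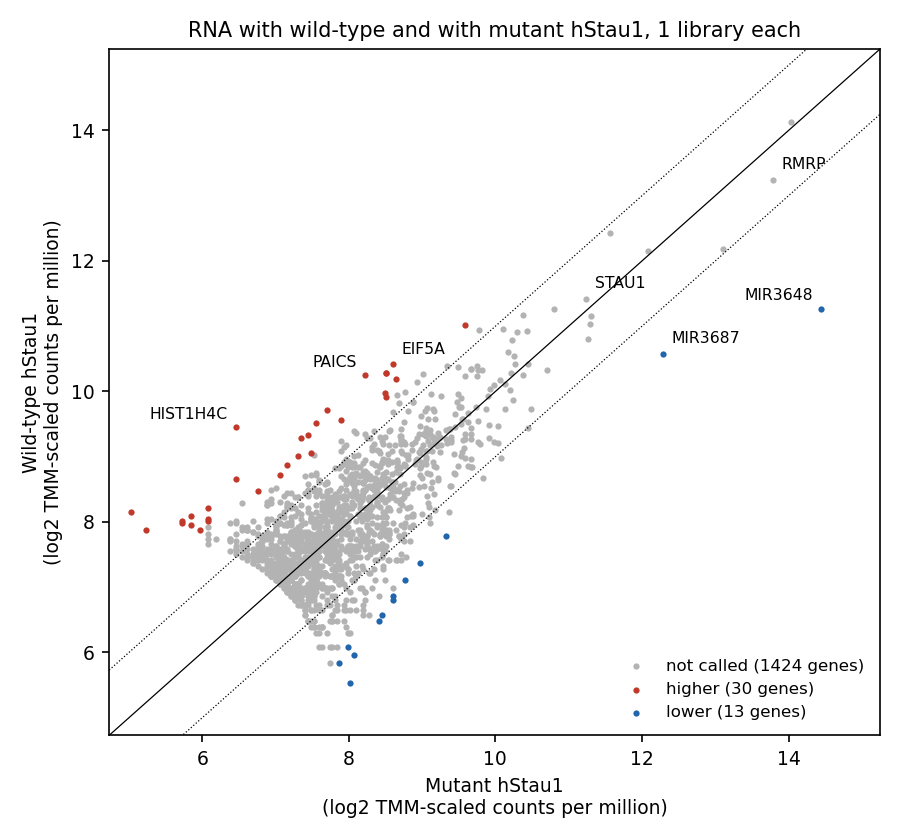
TMM-scaled counts (CPM, log2) of the 1467 measured genes with wild-type hStau1 (vertical axis) against mutant hStau1 (horizontal axis), 1 library each. The solid line marks equal levels and the dotted lines 2-fold; 30 genes were called higher (red) and 13 lower (blue), with MIR3648 and MIR3687 at the far right.

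Cytosolic ribosomal protein genes were the list farthest from random lists of matched expression. Of their 16 measured members, 5 were called higher with wild-type hStau1 and 0 lower, with a median log2 ratio of 1.06, at percentile 100 of 10000 such lists, whose central 95% range was -0.31 to 0.42. Their coding regions are short (median 684 nt), and random lists matched on coding length as well, chosen after the result was seen, had a median of 0.42 and a range of 0.14 to 0.80, with the list at percentile 99.9. RPL17 had 43 reads with wild type and 7 with mutant (log2 2.65, 1.56 to 4.13), and RPS27A had 48 and 13 (3.88-fold, 2.12 to 8.02). RPS3, named after its value was seen, had 139 and 47 reads (1.66, 1.19 to 2.18). RPS6 went the other way, with 35 and 62 reads (log2 -0.71, -1.36 to -0.09), and was not called. Summed over the list, these genes took 1.40% (1.34 to 1.46) of reads with wild type and 0.672% (0.633 to 0.713) with mutant. With upper-quartile scaling the number called higher fell to 2 of 16. Whether reads from similar sequences elsewhere entered or left these counts was not examined.

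Glycolysis genes had a median log2 ratio of 0.54 over 11 measured members, at percentile 97.2 of the random lists. GAPDH was the 1 member called higher, with 98 reads against 35 (log2 1.58, 1.03 to 2.20), and with upper-quartile scaling or in thinned libraries 0 were called. Endoplasmic reticulum chaperone and translocon genes had a median of 0.54 over 10 members, at percentile 97.7, and 0 were called. Histone genes had a median of 0.66 over 5 members, at percentile 96.1, or 67.1 with lists matched on coding length, with HIST1H4C, a histone H4 gene, called higher at 129 reads against 17 (7.99-fold, 4.92 to 14.5). The 21 cytoskeleton genes had a median of 0.28, with 1 called higher, the actin-severing factor CFL1 (86 reads against 28), and 0 with upper-quartile scaling. The 14 translation factors had a median of 0.26 and 1 call, EIF5A, but a median of -0.16 over 23 members with at least 10 reads. NDUFC2, a subunit of respiratory complex I, was the 1 call among 3 oxidative phosphorylation genes (134 reads against 37, log2 1.95), and its reads can be shared with the overlapping readthrough gene NDUFC2-KCTD14.

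Lists with medians on the mutant side held no called gene. Cell cycle genes had a median log2 ratio of -0.46 over 13 members, at percentile 0.6, with the replication helicase gene MCM3 at 21 reads against 67 (-1.54, -2.35 to -0.84). Chromatin regulators had a median of -0.31 over 16 members, at percentile 3.77, or 64.7 with lists matched on coding length, with the DNA methyltransferase gene DNMT1 at 14 reads against 51 (-1.72, -2.72 to -0.88) and the remodeller CHD4 at 52 against 131 (-1.21, -1.72 to -0.75). The 4 measured genes for double-stranded RNA-binding proteins had a median of -0.44, at percentile 6.89, among them ADAR, an RNA-editing enzyme (28 reads against 58). Published targets of Staufen1-mediated decay had 3 measured members and 0 calls, and ARF1, the best known of them, had 226 reads against 102 (log2 1.25, 0.91 to 1.61). Cytosolic chaperones, with a median of -0.11 over 12 members, and cholesterol and fatty acid synthesis genes, with 0.35 over 10, lay within the range of their random lists, as did the remaining lists with at least 5 measured members.

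**Figure D3:**
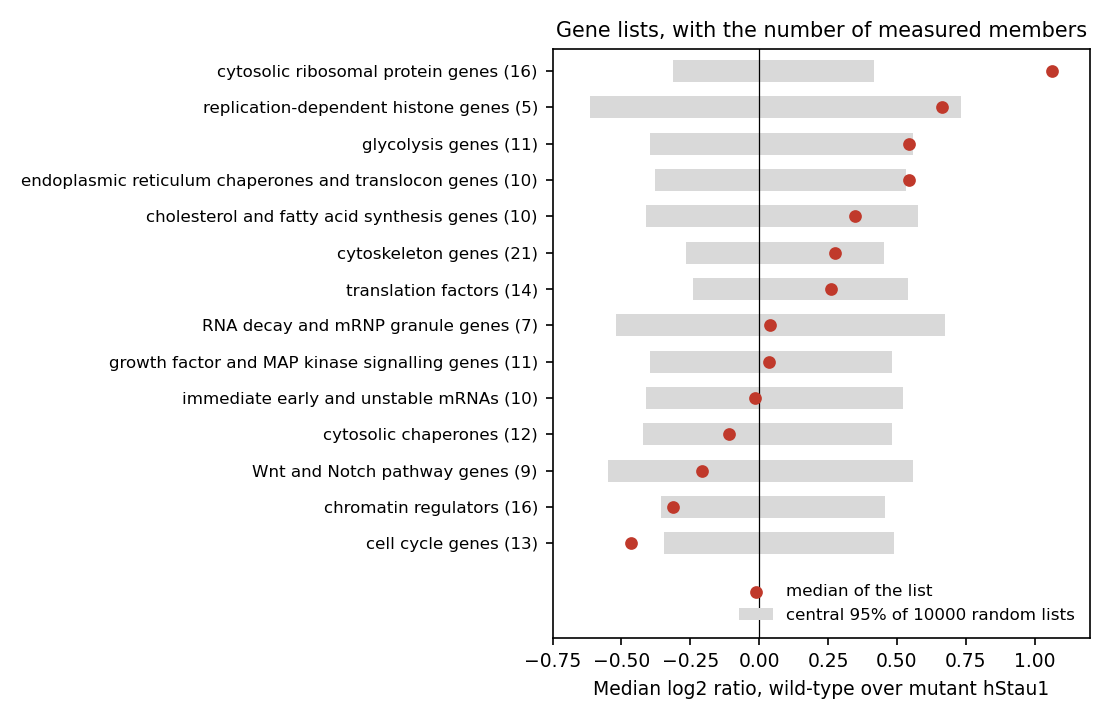
Median log2 ratio of wild-type over mutant hStau1 (red points) for the gene lists with at least 5 measured members, with the number measured in brackets and the central 95% of 10000 expression-matched random lists as grey bars. Ribosomal protein genes, at 1.06, endoplasmic reticulum genes, at 0.54, and cell cycle genes, at -0.46, lie outside their bars.

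The length of the coding region followed the difference between wild type and mutant more closely than any other property examined. Across 1433 coding genes the rank correlation (Spearman) of the log2 ratio with coding length was -0.48, with transcript length -0.39, with 3' UTR length -0.05 and with coding GC content 0.05. Genes are not independent replicates, so these values describe the libraries. In the decile with the shortest coding regions, up to 609 nt, the median log2 ratio was 0.58 and 19 of 144 genes were called higher. In the longest decile, from 3987 nt, it was -0.37, with 0 called higher and 4 lower. The median coding length was 501 nt for genes called higher, 2751 nt for those called lower and 1611 nt for the rest. Without the ribosomal protein genes the correlation was -0.47.

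**Figure D4:**
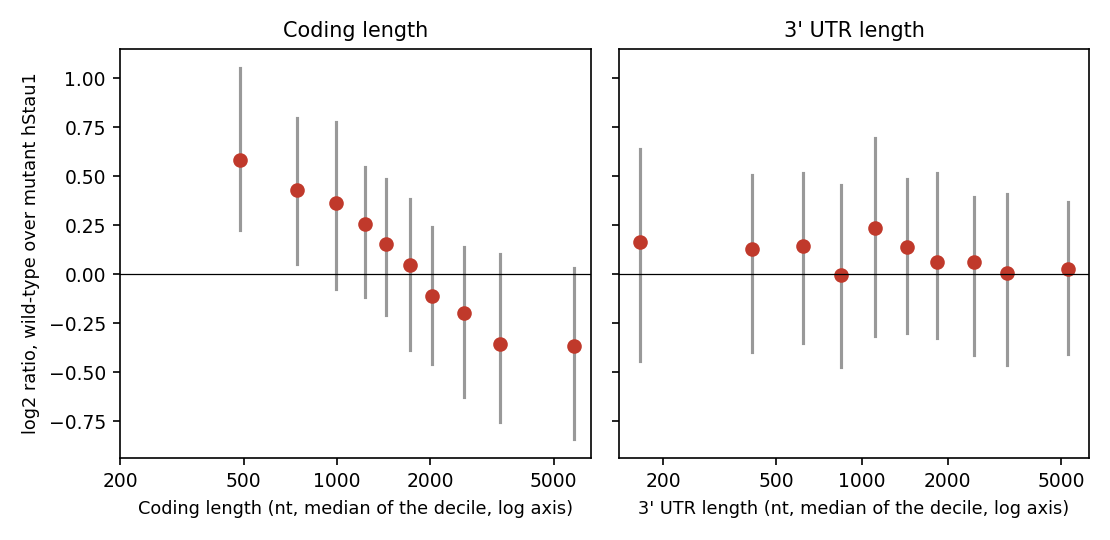
Median log2 ratio of wild-type over mutant hStau1 (points) and its quartiles (bars) in deciles of coding length and of 3' UTR length, both in nt on log axes. The median fell from 0.58 to -0.37 over the deciles of coding length and stayed between -0.00 and 0.24 over those of 3' UTR length.

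The comparison of the RNase T1 library with untreated wild-type hStau1 asks which RNAs hold more or fewer reads among the fragments that survived the enzyme. RMRP, the MTRNR2L genes and a limited set of mRNAs dominated the surviving fragments. Many mRNAs abundant without the enzyme, such as MAZ and EEF1A1, lost most of their reads. The MTRNR2L genes, whose values are uncertain, together had 15676 reads after RNase T1 and 4257 without it (log2 2.84, 2.80 to 2.89). XRCC2, a DNA repair gene (gene 7516, 7q36.1), had 603 reads after RNase T1 and 3 without it (log2 8.39, 7.06 to 10.90). MAGT1 (gene 84061, Xq21.1) had 9311 and 182 reads, a ratio of 99.5-fold with a log2 interval of 6.43 to 6.86. RMRP had 43681 and 1786, a ratio of 47.7-fold. The transcription factor MAZ fell from 1012 reads to 19 (log2 -4.73, -5.51 to -4.12), and EEF1A1, the elongation factor that delivers tRNA to ribosomes, from 366 to 9 (-4.31, -5.52 to -3.44).

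Of 766 measured genes, 164 were called higher and 491 lower after RNase T1, but the filter counts the RNase T1 reads. With at least 25 reads in the mutant library instead, 46 of 1578 genes were higher and 813 lower, and with at least 200 reads in the pair 53 were higher and 34 lower. The median log2 ratio was -2.81, and the genes called higher held 71.6% of the reads after RNase T1 against 8.07% before. The sign of the median depended on the filter. It was 0.25 over 16668 genes without a filter, 2.20 over 91 genes with at least 200 reads, and -2.59 with at least 25 mutant reads. Of the genes called lower, 54 had 0 reads after RNase T1, and 2 of those called higher had 0 reads without it, so their ratios are bounds only. The comparison holds the enzyme and the library preparation together, because fragmentation was omitted for the RNase T1 library per the labels' protocols. Scaling by total counts moved the median log2 ratio to -3.66, so all values of this comparison are relative to the scaling.

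The other RNAs that ranked highest after RNase T1 were mostly mRNAs for proteins of many kinds. MED18, a Mediator subunit, had 586 reads against 19 (log2 5.87, 5.25 to 6.65), and PSMB2, a proteasome subunit, had 1609 against 67 (5.54, 5.20 to 5.92). SSR3, of the translocon-associated protein complex, had 921 against 39 (5.51), GDPD1, a phosphodiesterase, 469 against 19 (5.55) and ZDHHC20, a palmitoyltransferase, 402 against 19 (5.33). CCDC125 (5.93), PRR11 (4.93) and the uncharacterised LOC339803 (5.50) also ranked among the top 12, as did NBPF11 (5.53), whose family shares sequence and whose count is therefore uncertain. At the other end stood MIR663, with 5 reads against 854 (log2 -6.32, -8.08 to -5.22), and the adhesion receptor gene LPHN1, with 1 read against 238 (-6.35, -12.24 to -4.44). SOX12, a transcription factor, had 6 reads against 357 (-4.82), RANGAP1, an activator of the Ran GTPase, 7 against 385 (-4.72), and CENPB, a centromere protein, 2 against 212 (-5.45, -8.82 to -3.89). HNRNPU, a nuclear RNA-binding protein, had 2 against 201 (-5.37, -8.74 to -3.82). NAT8L (2 against 229, -8.93 to -4.01), C9orf69 (3 against 237, -7.63 to -3.78), EIF5AL1 and the histone H3 genes completed the lowest 12.

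**Figure D5:**
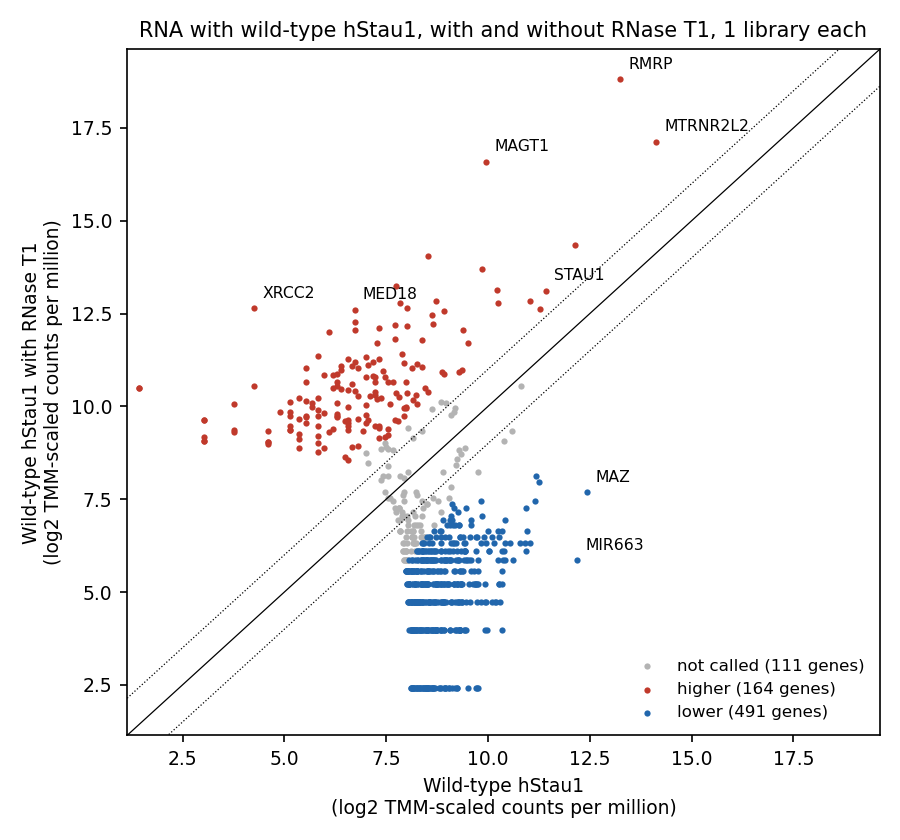
TMM-scaled counts (CPM, log2) of the 766 measured genes after RNase T1 (vertical axis) against untreated wild-type hStau1 (horizontal axis), 1 library each. The solid line marks equal levels and the dotted lines 2-fold; 164 genes were higher (red, led by RMRP, MAGT1 and XRCC2) and 491 lower (blue).

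Of 105 KRAB zinc finger genes, which encode DNA-binding repressors, the 4 measured were called higher, with a median log2 ratio of 4.39 at percentile 99.2 of the random lists, from ZNF562 (44 reads against 7, 3.53) to ZNF714 (173 against 11, 4.88, 4.06 to 5.97). These 4 passed the filter through their reads after RNase T1, so the filter selected on the outcome and the percentile is uncertain. With at least 10 reads, 8 of 14 KRAB genes were higher and 1 lower (median 3.20), and without a filter 10 of 86 were higher and 1 lower (2.37). The rise was not particular to KRAB genes, since olfactory receptor genes together went from 19 reads to 145 (log2 3.86, 3.20 to 4.67) and markers of skin, blood, liver and muscle from 2 to 18 (3.85, 2.07 to 7.29). Of the 4 measured structured noncoding RNAs, RMRP and the minor spliceosomal RNA RNU11 (75 reads against 1, log2 6.62, 4.67 to 12.52) were called higher, the small Cajal body RNA SCARNA2 was lower by at least 9.75-fold with 0 reads against 72, and RPPH1, the RNA of RNase P, was not called (140 against 330, -0.27, -0.57 to 0.02). STAU1 was called higher at 837 reads against 505 (log2 1.69, 1.53 to 1.86), a call lost with total-count scaling, where the log2 ratio was 0.84.

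In most housekeeping lists more genes were called lower than higher after RNase T1. Of 9 measured ribosomal protein genes 8 were called lower and 1 higher, RPL27A (118 reads against 25, log2 3.18, 2.57 to 3.89); the list median was -4.11, at percentile 2.65. Of 12 translation factors 10 were lower and 0 higher, with a median of -3.65. Of 8 cholesterol and fatty acid synthesis genes 7 were lower, with a median of -3.64, or -3.44 with the genes at 0 reads set to their bound. Of 13 cytoskeleton genes 10 were lower, with a median of -3.28. Of 8 glycolysis genes 5 were lower and 1 higher, PGK1 (63 reads against 13, 3.20). Of 8 endoplasmic reticulum genes 7 were lower and SSR3 was higher. Both measured targets of Staufen1-mediated decay were lower, ARF1 with 8 reads against 226 (-3.77, -5.09 to -2.85) and JUN with 5 against 115 (-3.43). Of 5 growth factor and MAP kinase signalling genes all 5 were lower, of 7 cell cycle genes 5, of 8 chromatin regulators 4 and of 5 immediate early genes 4. Apart from the KRAB list, the list medians lay within the central 95% range of random lists drawn from the same falling background, with the ribosomal protein genes at its lower edge.

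Genes higher after RNase T1 had longer 3' UTRs and lower GC content. Their median 3' UTR was 3226 nt against 1200 nt for genes called lower, and the median GC content of the transcript was 44.8% against 59.1%. Across 730 coding genes the rank correlation of the log2 ratio with transcript GC content was -0.47 and with coding GC content -0.39, and across 729 it was 0.35 with 3' UTR length. In the decile with the lowest coding GC content 56 of 73 genes were called higher, and in the decile with the highest 3 of 73. These values rest on the filter that counts the RNase T1 reads. With at least 25 reads in the mutant library, chosen after the result was seen, the correlations kept their sign but were weaker, at -0.24, -0.22 and 0.15 in the same order, and 16 of 155 genes in the decile with the lowest coding GC content were higher, against 0 of 155 in the highest.

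The RNase T1 library was also set against the mutant library. Of 816 measured genes 169 were called higher and 514 lower, with a median log2 ratio of -2.72. That median also turned with the filter, to 0.18 without one and 3.17 with at least 200 reads. Over the 626 genes measured in both comparisons of the RNase T1 library, 158 were higher in both and 356 lower in both, where independent lists give 43.2 and 226. The rank correlation was 0.96, against 0.67 in 100 simulations of unchanged libraries that share the RNase T1 counts. The simulated libraries hold counting error only, without any real difference between libraries. Both comparisons share the RNase T1 library, so its large differences alone raise the overlap and the correlation. The counts for independent lists and the 0.67 are therefore no reference for agreement of the comparisons.

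Across 655 genes measured in both, 8 were higher with wild type than with mutant and also higher after RNase T1, where independent lists give 2.52. Another 18 were higher with wild type and lower after RNase T1, where independent lists give 21. The rank correlation was -0.06, against -0.40 in simulated unchanged libraries that share the wild-type reads, and the covariance was 0.087 against -0.039. The simulated libraries hold counting error only, so the gap between these values does not measure a link between the comparisons. With the wild-type reads divided at random so that the comparisons shared none, 245 genes were measured, 3 were higher in both against 2.06 for independent lists, and the rank correlation was -0.05. The 8 genes, named because they are few and after their values were seen, were PAICS, PGAM5, NDUFC2, MRPL30, NUP43, QPCTL, BPNT1 and C11orf58. MRPL30, of the mitochondrial ribosome, had 47 reads with wild type, 13 with mutant and 431 after RNase T1, and NUP43, a nuclear pore protein, had 77, 26 and 691.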

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

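Rows that name no gene stayed outside all comparisons and still held reads above the 3 counts that a count of 0 allows. They carried 60 reads with wild-type hStau1, 65 with mutant hStau1 and 31 with wild-type hStau1 and RNase T1. With 1 library per group, no library could be tested for standing apart from others of its group.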

How the results depend on the processing

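No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. The filter on reads of the mutant library and the random lists matched on coding length were both chosen after seeing the data. In each sentence the numbers of genes stand in the order higher and lower, for wild type against mutant, RNase T1 against wild type and RNase T1 against mutant, beside main values of 30 and 13, 164 and 491, and 169 and 514. Without a filter they were 78 and 31, 573 and 1066, and 514 and 1051. With at least 10 reads they were 72 and 31, 349 and 1066, and 348 and 1051, and with at least 200 reads 8 and 2, 53 and 34, and 52 and 33. These filters change how many genes are measured. For wild type against mutant, intervals beyond 1.5-fold gave 75 and 45, beyond 4-fold 2 and 1, and the point estimate 124 and 90. DESeq2 size factors gave 7 lower genes, all among the 13. That scaling moves every log2 ratio and interval up by the same amount, and the median went from 0.09 to 0.18. Beyond 4-fold, 292 genes were lower for RNase T1 against wild type and 272 for RNase T1 against mutant. With at least 25 reads in the mutant library, 46 were higher and 813 lower for RNase T1 against wild type. The 8 genes higher with wild type and after RNase T1 became 14 without a filter or with at least 10 reads, 2 with at least 200 reads, 3 without the 100 features with most reads and 5 in thinned libraries. The 18 genes higher with wild type and lower after RNase T1 became 31, 31 and 4 under the 3 filters. The other 65 values of these results stayed within 1.5 times the main count or within the interval of the main median, among them the median of the ribosomal protein genes, which ranged from 0.95 to 1.23. Among further values of lists and their percentiles, named genes, correlations and shares, 716 stayed within their interval or margin and 67 moved. No named call changed direction, while list medians changed sign under some settings. For wild type against mutant these were mostly medians near 0, with translation factors at -0.16 with at least 10 reads and cell cycle genes at 0.33 with at least 200 reads (1 gene). For RNase T1 against wild type, endoplasmic reticulum genes went from -2.91 to 5.51 with at least 200 reads (1 gene) and structured noncoding RNAs from 2.65 to -0.27 with at least 10 reads. Of the 10 named genes called for wild type against mutant, the number still called was 8 with upper-quartile scaling, 9 in thinned libraries and 1 beyond 4-fold. Depth limits all 3 comparisons, since most genes hold fewer reads than the filter asks.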

Other observations

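The tests of the first pattern, that of the length of the whole RNA and those of the MIR3648 and MIR3687 reads were chosen only after the result was seen, as was the filter on reads of the mutant library; the tests of GC content and read level in the second pattern were written before their results were seen.

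Pairs of oppositely oriented Alu-like segments, which can fold into long double-stranded RNA, were common in the 3' UTRs of mRNAs that rose after RNase T1. Among measured genes 82 of 103 with an inverted pair were called higher (median log2 ratio 2.99), as were 17 of 23 with 2 or more segments in a single orientation (2.85), 24 of 65 with 1 segment (-1.20) and 20 of 532 without any (-3.39). With at least 25 reads in the mutant library, a filter that the RNase T1 reads do not enter, these were 22 of 60 (0.38), 4 of 30 (-1.59), 9 of 136 (-1.89) and 6 of 1301 (-2.74), in the same order. Inverted pairs occurred in 551 of the genes searched. With at least 50 reads in the pair, 145 coding genes were called higher, of which 143 had a searched 3' UTR. Inverted-pair genes accounted for 57.3% of these 143. Of the 8 genes higher both with wild type than with mutant and after RNase T1, 6 carried an inverted pair (75%). Among genes measured in both comparisons with a searched 3' UTR, 47 of 628 did (7.48%). Among searched coding genes higher after RNase T1 the share was 57.3%, the nearer baseline for a set of 8. The 6 genes were MRPL30, NUP43, QPCTL, NDUFC2, BPNT1 and PGAM5. PAICS had 3 segments in a single orientation and C11orf58 had 0. Between wild type and mutant, inverted-pair genes differed from matched genes by 0.26 (-0.05 to 0.64), an interval that reaches 0, and 6 of 63 were called higher and 0 lower. These are the same 6 genes, so this count is not a separate observation. Of 1202 genes without segments, 20 were called higher and 10 lower.

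Reads in genes that this line is not known to express were more frequent after RNase T1. Olfactory receptor genes, 374 in all, held 19 reads with wild type, 50 with mutant and 145 after RNase T1, a log2 ratio of 3.86 (3.20 to 4.67) for RNase T1 over wild type. With all libraries thinned to 139391 reads, 946, 1325 and 2987 genes had reads in that library alone, for wild type, mutant and RNase T1. Genes with any reads then numbered 11672, 12951 and 12909, so RNase T1 did not reach more genes than the mutant. Wild type and mutant resembled each other more than RNase T1, which by itself raises the count of genes found in RNase T1 alone. Whether the line expresses those genes was not examined. Small nuclear RNA genes held 33, 10 and 139 reads, and small nucleolar RNA genes 123, 75 and 80.

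Genes were first selected by at least 50 reads in the pair, which for RNase T1 selects on the outcome, so the tests used genes with at least 25 reads in the mutant library. There, inverted-pair genes exceeded genes without segments matched on 3' UTR length and coding GC content by 2.88 (2.16 to 3.97, 60 genes). A protected Alu duplex would give a difference above 0. Repeat reads placed in any gene with a segment would do so too, so this value cannot tell the explanations apart. Lower coding GC content alone would leave no difference within the 20% of genes with the lowest coding GC content, where it was 3.95 (2.05 to 4.50, 20 and 239 genes). These genes were not matched on 3' UTR length. The GC content of the 3' UTR itself did not enter the test, so its part stays open. Repeat reads placed in any gene with an Alu-like segment stay open: among genes with 2 segments, opposite orientations exceeded a single orientation by 2.60 (0.58 to 4.08, 16 and 19 genes), but the test had first been run with the original filter, where the difference was 0.42 (-0.83 to 3.11, 37 and 18 genes), and the filter was changed after that result was seen. Protection of inverted Alu pairs by hStau1 is a candidate explanation, as a hypothesis, and without an RNase T1 library of the mutant or of the tag alone it cannot be told from resistance of the duplex itself.

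mRNAs with short coding regions were higher with wild type than with mutant. GC content would remove the trend within 5 groups of genes of like GC content, and the weakest of the 5 rank correlations was -0.22 (-0.33 to -0.11). Read level would do so within 5 groups of like read number, and the weakest was -0.43 (-0.53 to -0.32). The length of the whole RNA would act through the 3' UTR as well. The rank correlation of 3' UTR length with the log2 ratio was -0.0498 (-0.10 to 0.00), against -0.48 (-0.52 to -0.43) for coding length. Transcript length, which includes the coding region, correlated at -0.39. The 3' UTR was taken from the longest matched transcript, which may not be the one expressed, so the length of the whole RNA stays open. The cause stays open, since a difference in RNA integrity or preparation between 2 single libraries was not tested.

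MIR3648 and MIR3687 reads, which may include RNA from ribosomal RNA precursors, were lower with wild type than with mutant. The 10% of coding genes with the highest transcript GC content (65.2% to 74.5%) did not follow them, with a median log2 ratio of 0.24 (0.17 to 0.35). The GC content of these loci was not measured, so fragments richer in GC than those genes stay open. Nuclear RNA carried into the mutant library stays open, since small nucleolar RNAs, at 0.82 (0.40 to 1.26), and small nuclear RNAs, at 1.78 (0.78 to 3.02), went the other way, while RMRP, at -0.55, and RPPH1, at -0.46, went the same way by less, and nuclear long noncoding RNAs stood at 0.25 (-0.21 to 0.72). Reads from genomic DNA would lower both loci as far as olfactory receptor genes, if all reads of those genes came from DNA. Olfactory receptor genes stood at -1.26 (-2.13 to -0.50), on 19 and 50 reads. MIR3648 differed from them by -1.91 (-2.69 to -1.03), further than DNA alone would give under that condition. Whether all olfactory receptor reads came from DNA was not tested, so DNA stays open for MIR3648. For MIR3687, at -0.45 (-1.24 to 0.43) from them, DNA stays open as well. The mutation itself is a biological explanation that the design names and that was not tested.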
